A study of Homo sapiens with 14 samples.

How the data were processed

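RNA of WI-38 human lung fibroblasts was measured on 14 Affymetrix human gene-level expression arrays, 1 array per sample. Per the labels, RNA was extracted with TRI reagent in biological duplicate, amplified and labelled as sense target across the whole transcript, and the cells were passaged weekly at a fixed seeding number. The labels put the arrays in 7 groups of 2: primary cells at passage 19, hTERT-immortalized cells with the letter A at passages 39, 50, 58, 67 and 95, and hTERT-immortalized cells with the letter B at passage 96. What the letters stand for is not given in the sources used here. The groups are written below as primary, A39, A50, A58, A67, A95 and B96, and an array is named by its label.

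The authors deposited 1 table of log2 values with 28869 rows, given to 2 decimals. The log base is read from the range of the values, which run from 0 to 14.27. Background correction, summarisation and normalization are not given in the sources used here. Array medians lay between 7.26 and 7.48 and array maxima between 13.97 and 14.27, so the arrays had been brought to a similar scale without being made equal. Between 3 and 20 rows per array were listed at exactly 0. The table holds neither detection calls nor background signals, so the precision of a value is limited by the number of arrays, and the point at which a dim row stops responding is unknown.

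Rows were named from the array platform's annotation, with symbols updated by gene ID through NCBI RefSeq's gene table. One symbol was found for 19310 rows, of which 19279 matched by gene ID, several symbols for 1752 rows, and none for 7807. Rows with several symbols were tested and never used to name a gene. For gene lists, the row with the highest mean over all arrays stood for its gene, which left 18377 genes. The genome build behind the table is not named, so no coordinates are given, and the RefSeq table served for names, chromosomes and neighbour relations.

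All values were used on the log2 scale as deposited, with no filter. A mean per group was fitted to all 14 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and groups were compared as contrasts, with the spread shared by the 7 groups. The residual degrees of freedom were 7 and the prior added 3.43. All 9 pairwise contrasts of interest and an F test over all groups were made, and p-values were adjusted by Benjamini-Hochberg over all rows at a threshold of 0.05. A linear trend was fitted to the 10 arrays labelled A as a slope per 10 passages. Gene lists fixed before the data were examined, 27 with markers of other cell types included, were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the 27 lists. Camera with an estimated correlation and fry were alternatives. All tests were two-sided.

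Genes were named by a rule fixed before the data were examined. For the 3 main contrasts it took the 10 largest rises and 10 largest falls among genes past the threshold with at least 1 log2 of change and no overlap between groups, and for other contrasts and the trend the 3 largest each way. It also took up to 4 members past the gene test from each list past its test, and TERT, CDKN2A, CDKN2B, CDKN1A, MKI67, DNMT1, DNMT3A and DNMT3B in every contrast. Because no pairwise contrast had a gene past the threshold, list members named for those contrasts were chosen by the size of their change after the values were seen.

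The fits were tested on simulated data made from the spread between arrays that share a label, and for the trend from the spread about the fitted line. In each contrast, 50 rows at each of 1, 2, 3 and 4 log2 were changed together, which eases the Benjamini-Hochberg threshold. Arrays were drawn independently, without the closer similarity across labels described below. Recovery in the measured data may therefore be lower. In A39 versus primary, the contrast recovered 40.0% of rows changed by 1 log2, 84.0% at 2 log2 and 100% at 3 log2. For A95 versus A39 the shares were 28.0%, 78.0% and 88.0%, and for B96 versus A95 they were 24.0%, 86.0% and 94.0%. The trend recovered 62.0% of rows with a slope of 0.2 per 10 passages and 92.0% at 0.4. Among the unchanged rows, 7, 14 and 7 were called in the 3 contrasts and 8 in the trend. In A39 versus primary, an extracellular matrix list moved by 1 log2 was called, with 0 of the other lists. Rows were simulated independently, so list members had no correlation, and the count of 0 does not bear on false list calls in the measured values.

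Alternatives fixed before the data were examined were leaving out each array, the replicate number as a block, quantile normalization, centring on array medians, a filter at the 30th percentile of row means, 1 row per gene, an intensity trend with a robust prior, array weights, and fits on the compared groups alone. The trend was also fitted with passage as a random block, on ranks of passage, and on passages 39 to 67. List tests of the trend, and fits without the arrays labelled A95 replicate 2 and B96 replicate 1, were added after the data were seen, and so was the test of symbol families among the falls. Correlations between arrays were computed over all rows. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.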

Results

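Gene expression was followed in WI-38 cells, a diploid fibroblast strain from human lung, along a long culture after immortalization with hTERT, the catalytic subunit of telomerase. The study's design text presents the culture as a course of evolution on a small scale, and the study's title concerns the random formation of differentially methylated regions. The 14 arrays comprised 2 labelled primary at passage 19, 10 labelled hTERT A at passages 39, 50, 58, 67 and 95, and 2 labelled hTERT B at passage 96. Each array gave 28869 log2 values.

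TERT was examined first, because its level separates primary from hTERT cells. The array labelled primary replicate 1 had a TERT value of 7.07, and the array labelled primary replicate 2 had 11.70. The 12 arrays labelled hTERT lay between 10.67 and 12.18, so the second array labelled primary lay inside the hTERT range. TERT averaged 9.39 ± 3.27 (SD, n = 2) in the arrays labelled primary and 11.90 ± 0.40 (SD, n = 2) in those labelled A39. One primary label therefore goes against the gene that checks it, and every comparison with the primary arrays below carries this limit.

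The labels of the other arrays did not follow the similarity of the arrays either. None of the 14 arrays, 0 by Pearson and 0 by Spearman correlation, was most similar to the array that shares its label. The 5 pairs of arrays that were each other's closest partner were primary replicate 2 with A39 replicate 1, A39 replicate 2 with A50 replicate 1, A50 replicate 2 with A58 replicate 1, A58 replicate 2 with A67 replicate 1, and A95 replicate 2 with B96 replicate 1. Their correlations across rows were 0.986 to 0.993, against 0.945 to 0.983 for the 7 pairs that share a label. Between 156 and 361 rows differed by at least 1 log2 within these 5 pairs, and between 454 and 2764 rows within the labelled pairs. All comparisons below keep the groups of the labels, so their spread includes these differences.

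**Figure D1:**
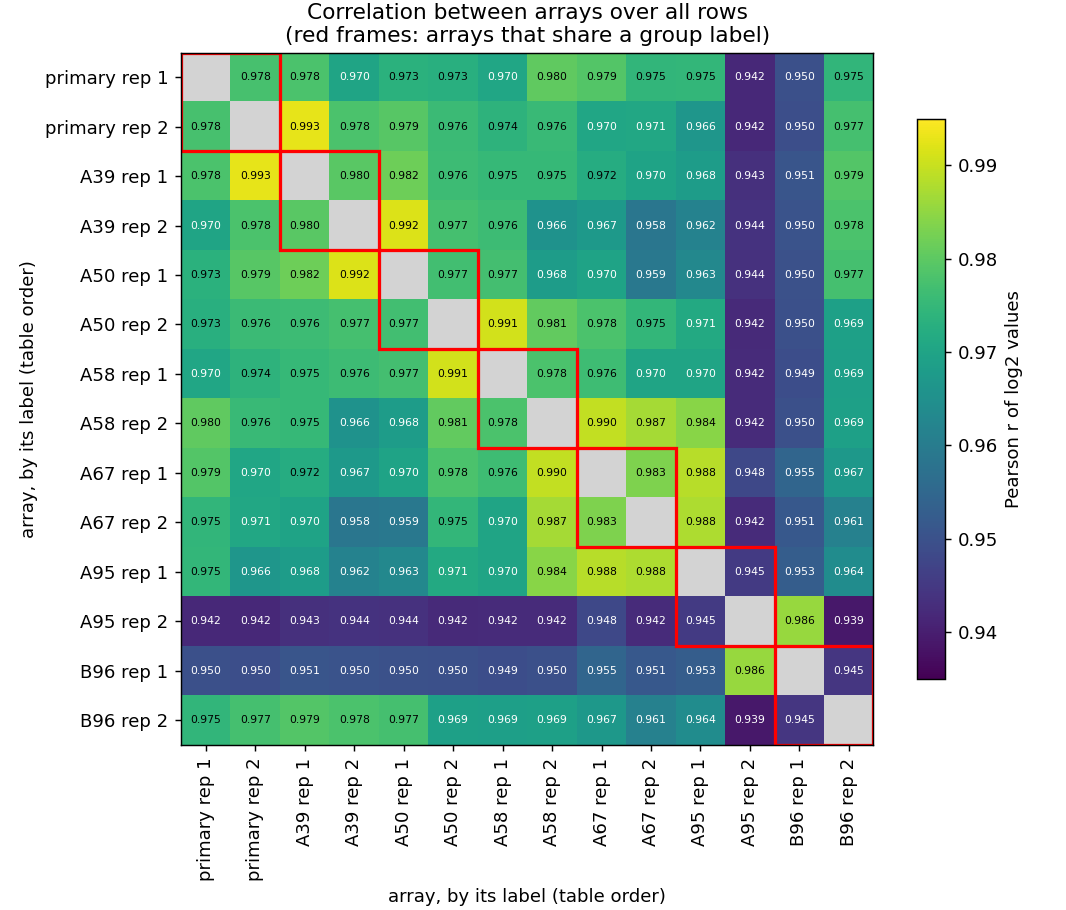
Pearson correlation of log2 values over all 28869 rows between the 14 arrays, in the order of the deposited table, with red frames around the arrays that share a group label and the diagonal left grey. The brightest cells, up to 0.993, lie across the borders of the frames, and the arrays labelled A95 replicate 2 and B96 replicate 1 form dark bands with a correlation of 0.986 to each other.

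Known regulators of growth arrest also differed within labels. CDKN2A, which encodes the cell cycle inhibitor p16, read 8.80 and 9.29 in the arrays labelled primary and between 9.25 and 9.59 in those labelled A39 and A50. In the arrays labelled A58 it read 9.42 and 8.10, in A67 7.85 and 6.33, in A95 6.54 and 7.84, and in B96 7.79 and 8.87. CDKN1A, which encodes the inhibitor p21, ran from 10.33 to 11.70, with 11.70 in A39 replicate 2 and 10.33 in A95 replicate 1. MKI67, a marker of cycling cells, was 8.79 and 8.84 in A39 replicate 2 and A50 replicate 1, and 10.91 and 10.88 in A67 replicate 2 and A95 replicate 1. DNMT1, the maintenance DNA methyltransferase, ranged from 9.51 in A58 replicate 1 to 10.92 in A67 replicate 2. The other genes followed in all contrasts, CDKN2B, DNMT3A and DNMT3B, had group means of 9.42 to 9.68, 7.49 to 7.73 and 6.89 to 7.28.

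**Figure D2:**
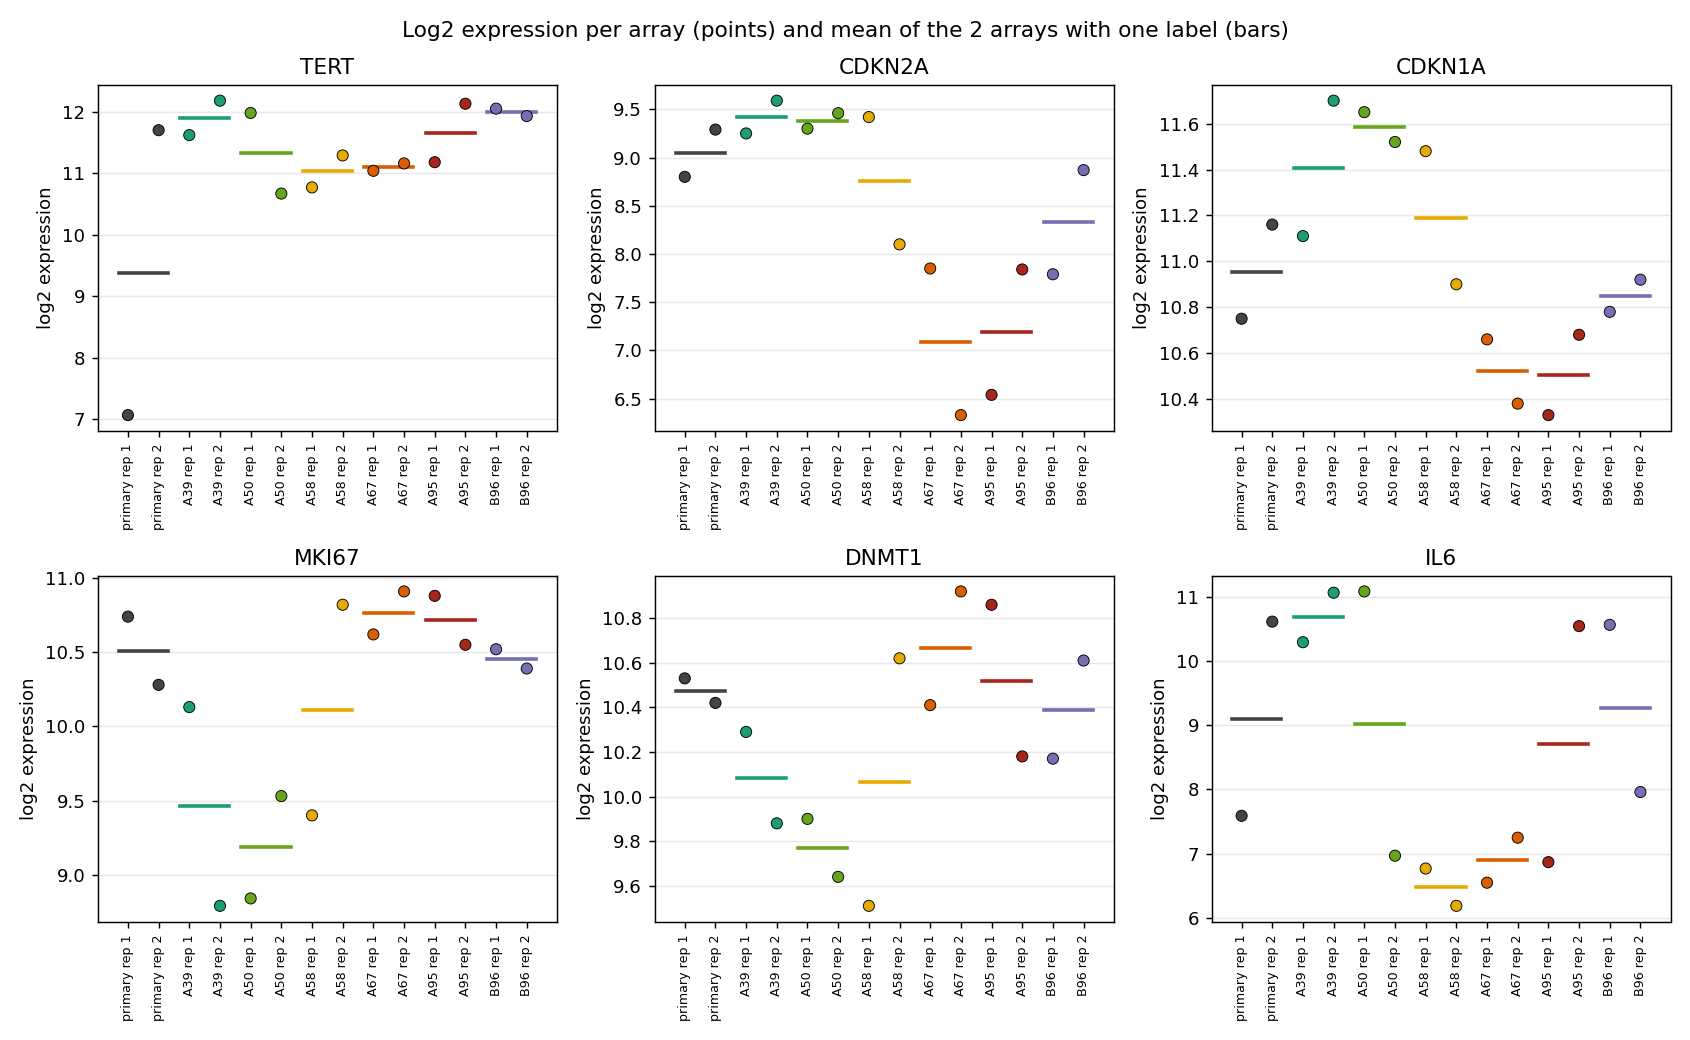
Log2 expression of 6 genes in the 14 arrays, named by label on the horizontal axis, with a point per array and a bar at the mean of the 2 arrays that share a label. TERT is 7.07 in the first array and at least 10.67 in all others, and IL6, shown as a secreted cytokine that differs within labels, reads 11.08 and 6.97 in the arrays labelled A50.

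The contrast of A39 with primary asks what differs at the earliest hTERT passage. Genes of mitosis were lower in the arrays labelled A39, with a median difference of -0.83 log2 and 31 of 31 measured genes negative. Genes of DNA replication were lower as well, with a median of -0.59 and 28 of 28 negative. BUB1B, a spindle checkpoint kinase, had a log2 difference of -1.14 ± 0.51 (SE), MKI67 of -1.05 ± 0.49 (-0.38 without A39 replicate 2 and -1.72 without A39 replicate 1), and RFC3, a subunit of the clamp loader of replication, of -1.01 ± 0.55. Interferon response genes were higher, with a median of 0.48 and 20 of 23 positive, among them IFI6 at 1.64 ± 1.05 and IFI44 at 1.38 ± 1.12. Genes of the unfolded protein and amino acid stress response had a median of 0.25 with 22 of 23 positive, p53 target genes 0.14 with 21 of 24 positive, and MHC and antigen presentation genes 0.40 with 6 of 7 positive. TGF-beta response genes had a median of -0.21 with 11 of 18 negative, including NOX4, an NADPH oxidase, at -1.24 ± 0.47.

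In camera's test these 7 of 27 lists passed, 4 upward and 3 downward, with adjusted p from 2.0e-24 for mitosis to 0.033 for MHC and antigen presentation. All 7 were lost with an estimated correlation, where the smallest adjusted p = 0.754 (mitosis and TGF-beta response) and the adjusted p = 0.804 for the other 5, and with fry, where the smallest adjusted p = 0.857. Limma called 0 of 28869 rows, and adjusted over the list alone it called 0 members in each of the 7 lists. At an unadjusted p under 0.05 it found 347 rows, where 1443 would be due to chance. Primary replicate 2 and A39 replicate 1, mutual closest partners, lie on opposite sides of this contrast, so few calls cannot show an absence of change. The count of 0 over all 28869 rows also held with the replicate block, quantile normalization, array weights and the robust prior. Mitosis and DNA replication passed with each of the 4 arrays left out, with medians of -0.27 and -0.17 without A39 replicate 2 and of -1.36 and -0.98 without A39 replicate 1. Leaving out the array labelled primary replicate 1 turned the medians to -0.15 for interferon response, -0.025 for MHC and antigen presentation and -0.095 for the stress response, of which the first and the last then passed downward, and without primary replicate 2 they were 1.22, 0.69 and 0.66. Of these 4 cases the p53 targets passed only that without primary replicate 2 (median 0.26). Their median was 0.085 without primary replicate 1 and 0.08 without A39 replicate 2. TGF-beta response was lost without A39 replicate 2 or with the filter on dim rows (median -0.093) and had a median of -0.068 without primary replicate 2. With A39 replicate 1 left out 4 lists passed, and the calls of interferon response, MHC and antigen presentation, the stress response and p53 targets were lost at medians of 0.42, 0.35, 0.28 and 0.24. With primary replicate 2 left out limma called 6 rows, and TERT was 4.83 log2 higher in A39 with an adjusted p of 0.033, against 2.52 ± 1.10 (SE, adjusted p = 1.00) with both arrays.

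The contrast of A95 with A39 spans the passage course. Genes of DNA replication had a median difference of 0.86 log2 with 28 of 28 positive, and genes of mitosis 0.87 with 31 of 31 positive. CCNE2, a cyclin of the G1/S transition, had a difference of 1.64 ± 0.58 (SE), CDC6, a licensing factor, of 1.40 ± 0.49, and FOXM1, a transcription factor of mitotic genes, of 1.22 ± 0.38. p53 target genes had a median of -0.46 with 21 of 24 negative, and CCNG1, TP53INP1 and SESN2 had differences of -1.66 ± 0.52, -1.36 ± 0.44 and -1.21 ± 0.37. Genes of the unfolded protein and amino acid stress response had a median of -0.47 with 22 of 23 negative, including ASNS, the asparagine synthetase, at -1.55 ± 0.46. SESN2 belongs to both lists.

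Other lists passed camera's preset test between the same ends of the course, and none of them passed with an estimated correlation (adjusted p = 0.592 to 0.691). Extracellular matrix genes had a median of -0.49 with 26 of 35 negative, among them LUM at -1.56 ± 0.54, MFAP4 at -1.44 ± 0.41 and COL12A1 at -1.14 ± 0.38. Interferon response genes had a median of -0.46 with 17 of 23 negative, including MX1 at -2.66 ± 0.89. TGF-beta response genes had a median of -0.36 with 12 of 18 negative, contractile genes -0.19 with 13 of 17 negative, and glycolysis and hypoxia genes -0.043 with 14 of 26 negative and 11 positive. Germline and cancer-testis genes, which most somatic cells keep silent, had a median of 0.27 with 22 of 25 positive. SSX1 had a difference of 1.86 ± 0.67, MAGEC2 of 1.40 ± 0.49 and MAGEC1 of 1.01 ± 0.28. For MAGEB2 it was 3.02 ± 1.71, and the gene read 4.96 and 9.95 in the 2 arrays labelled A95. The difference was -2.23 ± 0.61 for CDKN2A and -0.90 ± 0.26 for CDKN1A, both with an adjusted p of 0.528.

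Camera passed 10 of 27 lists here, 3 upward and 7 downward, with adjusted p from 1.1e-09 for p53 targets to 0.040 for contractile genes. None passed with an estimated correlation, where the smallest adjusted p = 0.592, or with fry, where the smallest adjusted p = 0.177. Limma called 0 of 28869 rows, with 2660 at an unadjusted p under 0.05 against 1443 due to chance. Adjusted over the list alone, 9 of 24 p53 target genes and 2 of 10 cell cycle inhibitors and tumour suppressors passed. With A95 replicate 1 left out limma called 4 rows and 6 lists passed, the mitosis median was 0.38 with a camera adjusted p of 0.268, and the interferon median was 0.030 with an adjusted p of 0.922. With A39 replicate 2 left out the mitosis median was 0.29 with an adjusted p of 0.230, and with A39 replicate 1 left out 6 lists passed. The p53 targets, the stress response and DNA replication passed with each of the 4 arrays left out, the last with a median of 0.49 to 1.36. The germline call was lost without A95 replicate 2 (median 0.22), an array in which that list stood at 0.51 and which is the closest partner of B96 replicate 1. The TGF-beta call was lost without A95 replicate 2 or A39 replicate 1 (median -0.26 in the latter case). Contractile genes were lost without A39 replicate 2 (median -0.095) or A95 replicate 1, where the median of -0.26 was larger in size than with all arrays. Quantile normalization ended both calls, at medians of -0.37 and -0.24, and that of glycolysis and hypoxia (-0.023), and the filter on dim rows ended those of TGF-beta (median -0.17) and glycolysis and hypoxia. Glycolysis and hypoxia genes were lost without A39 replicate 1 or A95 replicate 1, at medians of -0.0425 and -0.04, close to that with all arrays. Interferon genes were lost in the same cases, at medians of -0.275 and 0.030. The extracellular matrix was lost without A39 replicate 1 and had a median of -0.22 without A95 replicate 1.

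**Figure D3:**
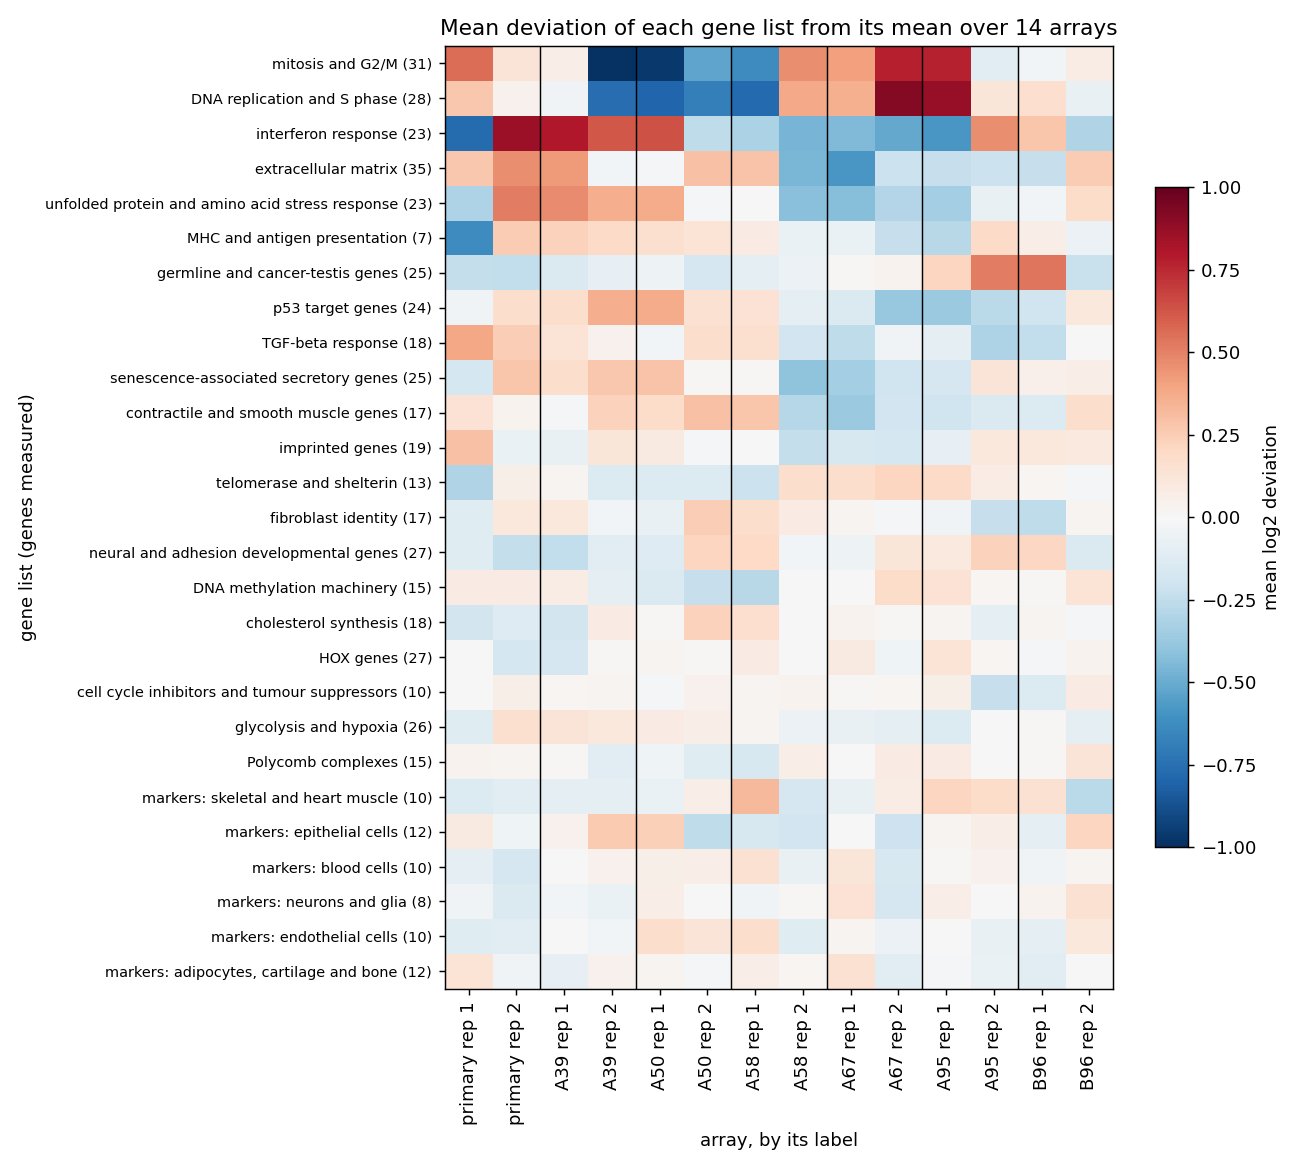
Mean log2 deviation of each gene list from its own mean over the 14 arrays, by array label, with the number of measured genes in brackets and lists of other cell types at the bottom. The mitosis list runs from -0.99 in A39 replicate 2 to 0.78 in A67 replicate 2, and the interferon list is -0.77 in primary replicate 1 and 0.86 in primary replicate 2.

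Gene lists also differed within labels. The interferon response list deviated by -0.77 in primary replicate 1 and by 0.86 in primary replicate 2. The mitosis list stood at 0.063 and -0.99 in the arrays labelled A39, and at -0.63 and 0.46 in those labelled A58. The germline and cancer-testis list stood at 0.21 and 0.51 in the arrays labelled A95, and at 0.54 and -0.22 in those labelled B96. Markers of other cell types were examined as well. The lists of endothelial cells, blood cells, neurons and glia, epithelial cells, skeletal and heart muscle, and adipocytes, cartilage and bone passed in none of the 3 contrasts or the trend. Their ranges over the 14 arrays were 0.30, 0.32, 0.32, 0.51, 0.60 and 0.27 log2.

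The 4 steps between neighbouring labelled passages gave 0 called rows each in limma. At an unadjusted p under 0.05 there were 230 rows for A50 versus A39, 284 for A58 versus A50, 387 for A67 versus A58 and 904 for A95 versus A67, against 1443 due to chance. The steps from A39 to A67 each set mutual closest partners in opposite groups, while arrays that share a label differed more. Differences between these groups are thus reduced against the spread, and the counts cannot show an absence of change. In the step from A58 to A67 the difference was -1.67 ± 0.61 (SE, adjusted p = 1.00) for CDKN2A and 0.66 ± 0.49 for MKI67, which read 9.40 and 10.82 in the arrays labelled A58 and 10.62 and 10.91 in those labelled A67. For A95 versus A67, limma called 6 rows without A95 replicate 1 and 1 row without A67 replicate 1. The F test for any difference among the 7 groups called 0 rows, with 1333 at an unadjusted p under 0.05.

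Passage was next taken as a number over the 10 arrays labelled A. Limma found a linear trend in 81 rows at an adjusted p under 0.05, of which 69 fell and 12 rose with passage. The fit takes the 10 arrays as independent. However, 3 pairs of mutual closest partners lie among them at adjacent labelled passages, so its p-values may be too small. The smallest adjusted p was 0.039, and 5405 rows had an unadjusted p under 0.05 against 1443 due to chance. Rows with 1 symbol made up 58 of the 81, with 52 falls and 6 rises. ZNF626, a zinc finger gene on chromosome 19, fell by 0.51 ± 0.085 (SE) per 10 passages on one row, and its other row had a slope of -0.28. SERPINF1, which encodes the secreted factor PEDF, fell by 0.48 ± 0.081. SNORD116-21, a small nucleolar RNA of an imprinted cluster, fell by 0.46 ± 0.076. Rows of this repeated family can share probes, so its row is uncertain. ACSL5, a fatty acid activating enzyme, rose by 0.56 ± 0.080, SPIN4 by 0.31 ± 0.050 and LETM2 by 0.29 ± 0.039.

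**Figure D4:**
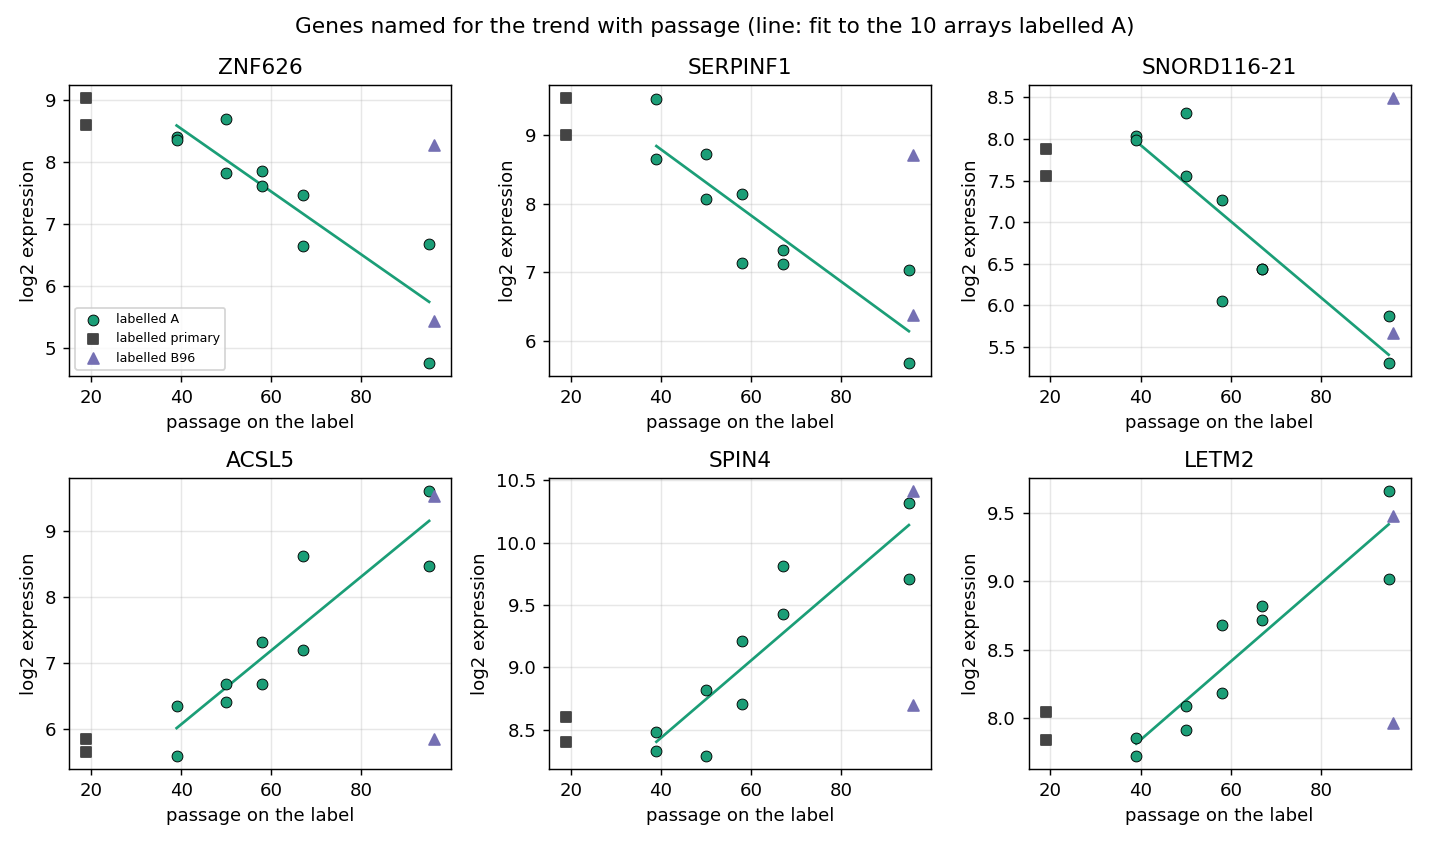
Log2 expression against the passage on the label for the 6 genes named by the trend, with circles for the 10 arrays labelled A, squares for primary, triangles for B96, and the fitted line through the circles. ACSL5 reads 5.60 and 6.35 in the arrays labelled A39 and 8.46 and 9.59 in those labelled A95, and the 2 arrays labelled B96 read 9.52 and 5.85.

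Zinc finger genes, a family chosen after the values were seen, were among the falls. Of 49 genes that fell, 12 carried a ZNF symbol, or 24.5%, against 2.68% of the 18377 genes tested. Because the family was picked for its frequency, all 91 families of at least 20 genes whose symbols share their leading letters (at least 2) were tested by two-sided Fisher's exact test. ZNF was the 1 family past the threshold, with an adjusted p of 4.1e-07 over the 91, and genes are not independent replicates in this test. On chromosome 19 lie 10 of the 12, among them ZNF506 with a slope of -0.36 ± 0.043 (SE), ZNF570 with -0.32 ± 0.041 and ZNF790 with -0.36 ± 0.057. Other falls included CHFR, a mitotic checkpoint ubiquitin ligase, with -0.37 ± 0.054, the secreted factor DKK3 with -0.30 ± 0.039, and the small heat shock protein HSPB6 with -0.31 ± 0.042. TNFRSF10B, a death receptor among the p53 targets, fell by 0.20 ± 0.035 and was the 1 list member past the threshold.

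Among the lists, camera passed 9 of 27 for the trend, 3 upward and 6 downward, in a test added after the data were seen. None of the 9 passed with an estimated correlation, where the smallest adjusted p = 0.449 (germline and p53 targets), while fry passed 2, germline and p53 targets, each with an adjusted p of 0.034. DNA replication genes had a median slope of 0.21 per 10 passages with 28 of 28 positive, and mitosis genes 0.20 with 31 of 31 positive. Germline and cancer-testis genes had a median slope of 0.054 with 23 of 25 positive. The p53 targets had -0.096 with 22 of 24 negative, the stress response -0.084 with 21 of 23 negative, and the extracellular matrix -0.10 with 29 of 35 negative. Contractile, TGF-beta response and interferon genes had median slopes of -0.073, -0.059 and -0.051. Adjusted over the list alone, 16 of 24 p53 targets, 10 of 28 replication genes and 0 of 31 mitosis genes passed. In lists that camera did not pass, the count was 5 of 17 for fibroblast identity and 5 of 27 for neural and adhesion genes. It was 0 of 25 for senescence-associated secretory genes. Over all 28869 rows, 5405 had an unadjusted p under 0.05, so such counts are not particular to the lists that passed. With each of the 10 arrays left out, camera still passed replication, mitosis, p53 targets, the stress response and the extracellular matrix, with median slopes of 0.30 for replication and 0.29 for mitosis without A95 replicate 2. The germline call was lost without A95 replicate 2, with a median slope of 0.022. Interferon genes were lost without A39 replicate 1 (-0.0021), A39 replicate 2 (-0.024) or A95 replicate 1 (-0.026), and had a slope of -0.19 without A95 replicate 2 and -0.035 without A50 replicate 1. TGF-beta response was lost without A95 replicate 2 (-0.033), A39 replicate 1, A50 replicate 2 or A67 replicate 1, and contractile genes without A39 replicate 2, A50 replicate 2 or A95 replicate 1. Both were also lost with quantile normalization, at slopes of -0.058 and -0.061, and TGF-beta response with the filter on dim rows (-0.030).

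The number of rows past the threshold varied with the array left out. It was 571 without A95 replicate 1, with 74 of the 81 among them, 72 without A67 replicate 2, with 54 of the 81, and 1 without A50 replicate 1. It was 0 in the other 7 cases, without either A39 or A58 array, A50 replicate 2, A67 replicate 1 or A95 replicate 2. All 81 slopes kept their sign in each case, and the slope per 10 passages stayed between -0.62 and -0.41 for SERPINF1 and between 0.49 and 0.66 for ACSL5. The rows had been chosen for their slopes in these same arrays, so the kept signs are not a test of the trend. On passages 39 to 67 alone, 0 rows passed.

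The contrast of B96 with A95 sets the letters side by side at nearly the same passage. Genes of DNA replication had a median difference of -0.42 log2 with 28 of 28 negative, and genes of mitosis had a median of -0.29 with 31 of 31 negative. p53 targets had a median of 0.22 with 20 of 24 positive, among them SESN1 at 0.52 ± 0.21 (SE) and TP53INP1 at 0.97 ± 0.44. Extracellular matrix genes had a median of 0.23 with 28 of 35 positive, including BGN at 1.17 ± 0.53, and the stress response 0.26 with 18 of 23 positive. CDKN2A had a difference of 1.14 ± 0.61 (adjusted p = 1.00), which was 0.49 without A95 replicate 1, 0.60 without B96 replicate 2 and 1.79 without A95 replicate 2. Camera passed these 5 lists, with adjusted p from 2.1e-06 to 0.0030, and 0 passed with an estimated correlation (smallest adjusted p = 0.865) or with fry (smallest adjusted p = 0.956). Limma called 0 rows, with 659 at an unadjusted p under 0.05 against 1443 due to chance. Arrays A95 replicate 2 and B96 replicate 1 are each other's closest partner, and without the array labelled A95 replicate 1 none of the 5 passed, 1 other list did, the DNA replication median was -0.043 and the mitosis median turned to 0.085. Without A95 replicate 2 these medians were -0.91 and -0.68. Without B96 replicate 2, limma called 3 rows and the 2 lists that passed were DNA replication and mitosis. Without B96 replicate 1 mitosis and the stress response were lost, and the medians of p53 targets and the extracellular matrix were 0.40 each, against 0.078 and 0.10 without B96 replicate 2.

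The late passages were also set against primary cells. A95 versus primary gave 0 called rows in limma, with 2914 at an unadjusted p under 0.05, and CDKN2A had a difference of -1.86 ± 0.61 (SE, adjusted p = 0.489). B96 versus primary gave 0 called rows, with 1981 at an unadjusted p under 0.05, and TERT had a difference of 2.61 ± 1.10 (adjusted p = 0.695). Without the array labelled A95 replicate 1 the first count was 9, and without B96 replicate 2 the second was 6. The log2 differences of A95 versus A39 and B96 versus primary, which share no array, correlated across rows with r = 0.448 and rho = 0.410, and 66.3% of rows had the same sign. Rows are not independent replicates. Without the array labelled A95 replicate 2 the r was 0.070, and without B96 replicate 1 it was -0.057. It was 0.231 without primary replicate 2 and 0.286 without A39 replicate 1, so the size of the relation depended on single arrays of each of the 4 groups. A95 replicate 2 and B96 replicate 1 are each other's closest partner, and so are primary replicate 2 and A39 replicate 1. Each contrast holds an array of both pairs on the same side, so the contrasts are not independent. The r therefore does not measure agreement between separate comparisons.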

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

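No test in this part was chosen only after the result was seen. The 5 gene lists below passed a direct test of B96 against A95 by camera with the preset correlation, and with an estimated correlation each had an adjusted p of 0.865. The arrays labelled A95 replicate 2 and B96 replicate 1 are each other's closest partner, with a correlation of 0.986, above that of any of the 7 pairs that share a label. DNA replication genes had an adjusted p of 2.1e-06 with a median of -0.42 log2 for B96 minus A95. p53 target genes had an adjusted p of 1.4e-04 with a median of 0.22. Extracellular matrix genes had an adjusted p of 0.0014 with a median of 0.23, and mitosis genes had an adjusted p of 0.0014 with a median of -0.29. The unfolded protein and amino acid stress response had an adjusted p of 0.0030 with a median of 0.26. Without the array labelled A95 replicate 1, none of the 5 passed, the DNA replication median was -0.043 and the mitosis median turned to 0.085. Without B96 replicate 2, 2 of the 5 passed, and without B96 replicate 1, 3 of the 5. Groups of 2 arrays are too small for a search for outlying arrays within a group.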

How the results depend on the processing

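List tests on the trend were chosen after the data were seen, and so were the fits without the arrays labelled A95 replicate 2 and B96 replicate 1, which called 0 rows in the 3 main contrasts and the F test. The cause of the changes below was not tested, except that leaving out arrays leaves fewer samples. With fits on the compared groups alone, A95 versus A39 called 2 rows and A58 versus A50 called 1. Quantile normalization gave 1 row for B96 versus primary. With an array left out, called rows ranged from 0 to 6 for A39 versus primary, 0 to 4 for A95 versus A39, 0 to 6 for A95 versus A67, 0 to 3 for B96 versus A95, 0 to 9 for A95 versus primary and 0 to 6 for B96 versus primary. Other settings left the pairwise counts and the F test at 0.

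The trend's 81 rows became 159 with quantile normalization, 429 with median centring, 271 with the filter on dim rows, 174 with 1 row per gene, 132 with the intensity trend and robust prior, 2171 with array weights, 729 with passage as a random block (consensus correlation -0.164) and 489 on ranks. The random block groups arrays by label, so it does not account for the closest partners across labels. On passages 39 to 67 the count of rows was 0, and with an array left out it ranged from 0 to 571. Falls made up 85.2% of the 81 rows, in which rows with identical values count separately, and 87.4% with 1 row per gene. Their share was 94.2% with median centring, 69.7% with the random block and 57.4% with array weights. All 81 slopes kept their sign in every setting that tested them, which is no separate test, because the rows were chosen for their slopes in the same arrays.

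The replicate numbers did not pair the arrays. Over the 21 pairs of groups, the deviations of same-numbered arrays correlated from -0.529 to 0.196, and 4 correlations exceeded 0.1. With the replicate block, the trend had 74 rows, of which 62 were among the 81, and the 9 pairwise contrasts had 0.

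With an estimated correlation, 0 lists passed in the 3 contrasts and in the trend. Fry passed 0 in the 3 contrasts and 2 in the trend. With an array left out, passing lists ranged from 4 to 9 for A39 versus primary, 6 to 9 for A95 versus A39, 1 to 6 for B96 versus A95 and 7 to 9 for the trend. Quantile normalization ended the calls of contractile and TGF-beta genes in A95 versus A39 and the trend, and of glycolysis in A95 versus A39. The filter on dim rows ended those of TGF-beta genes in A39 versus primary, A95 versus A39 and the trend, and of glycolysis in A95 versus A39. In A39 versus primary, the median with an array left out ranged from -0.15 to 1.22 for interferon response, -0.025 to 0.69 for MHC and antigen presentation and -0.095 to 0.66 for the stress response, with the negative values without primary replicate 1. In B96 versus A95, the mitosis median ranged from -0.68 to 0.085, the latter without A95 replicate 1. Of 333 values of lists under other settings, 221 kept their side of the threshold and direction, 108 lost significance and 4 reversed in camera's direction. Among the 108, the interferon median in A95 versus A39 turned from -0.46 to 0.030 without A95 replicate 1. The correlation of A95 versus A39 with B96 versus primary went from 0.448 to 0.070 without A95 replicate 2 and to -0.057 without B96 replicate 1, was 0.231 without primary replicate 2 and 0.286 without A39 replicate 1, and was at most 0.609 with another array left out. Of 192 values of followed genes, 191 kept their side of the threshold, 17 of them with another sign while uncalled, and TERT in A39 versus primary passed without primary replicate 2. The 6 genes named for the trend lost their call in 57 of 114 values and reversed in 0. No background signal is given, so no limit from signal over background can be set.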

Other observations

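The tests of displaced or rotated columns, of hybridisation batches across label borders and of markers of other cell types were chosen after their results were seen, and so were the slopes over all zinc finger genes, the counts of orders at an unadjusted p and of orders that keep the partner pairs, and the genes named in this part. The pairs counted in the batch test were also redefined after its result was seen, with a count of 0 before and after. Several genes read far from the other arrays in the pair labelled A95 replicate 2 and B96 replicate 1. IL2, a T cell cytokine, read 10.19 and 9.48 there, and 2.25 to 3.60 in the other 12. MAGEB2, a cancer-testis gene on the X chromosome, read 9.95 and 10.00 there and 4.02 to 4.96 elsewhere. ZNF671 read 10.98 and 10.89 there and 5.84 to 6.68 elsewhere. EPB41L3, a membrane skeleton gene, read 5.22 and 5.73 there and 7.38 to 10.62 elsewhere. NDN, an imprinted gene, read 10.20 in primary replicate 1, 8.74 and 8.73 in that pair, and 4.81 to 7.11 in the rest.

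Other genes changed level between arrays that share a label. ITGA8, an integrin subunit, read 10.87 and 5.19 in the arrays labelled A50, TNFRSF21 read 10.58 and 5.38, and THBS2, a matrix protein, read 10.16 and 6.79. PCDHB5, a clustered protocadherin, read 10.99 and 6.20 in the same arrays. ELAPOR2 read 7.56 and 11.22 in the arrays labelled A58. LIMCH1 read 6.01 and 9.92 in those labelled A67, and 9.80 in A95 replicate 1. AMZ2P1, a pseudogene, read 12.13 to 12.27 in primary replicate 2, both A39 arrays and A50 replicate 1, 11.96 in B96 replicate 2, and 5.79 to 6.79 in the other 9 arrays.

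The first pattern is that 0 of 14 arrays correlated best with the array of the same label. All 5 pairs of mutual best partners lie at neighbouring positions of the deposited table. A random order would give this with an exact probability of 1.3e-04. The table is ordered by group and passage, so correct labels could give neighbouring partners too, and this probability does not bear on displacement. Each pair crosses a label border, so labels displaced by 1 position against the columns are a candidate explanation. Displacement would also pair A67 replicate 2 with A95 replicate 1. The former correlated best with the latter (0.9876), but A95 replicate 1 correlated best with A67 replicate 1 (0.9884). These correlations are close and do not decide which array is the partner of A95 replicate 1. A rotation of all columns is argued against, since TERT differed by 4.86 log2 between the first and the last array, and by at most 0.25 within the mutual pairs. Batches of neighbouring arrays on top of correct labels are argued against too, because in 0 of 5 cases did the arrays that share a label have the highest of the 4 correlations between neighbouring pairs. Which cells the first and last arrays hold stays open, and no biological explanation was tested.

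The second pattern is that the arrays labelled A95 replicate 2 and B96 replicate 1 deviate together, by over 1 log2 from the median of the other 12 in 639 rows upward and 648 downward. A scale difference of the whole arrays does not account for most of these 1287 rows, because 89.3% remained after quantile normalization. Array medians were already similar, so this test had little scale to remove. Both arrays had a distribution unlike the other 12, with 4 and 3 rows at 0 against 12 to 20. Their maxima were 13.97 and 13.98, against at least 14.15. Whether the cells or the processing gave this difference was not tested. RNA of the 6 other cell types with marker lists is argued against, since no list stood higher in both arrays than in all others, the closest with a difference of -0.15 log2. A labelling or hybridisation batch shared by both arrays cannot be told apart from a difference of the cells. Rows without a symbol made up 36.8% of the deviating rows (95% exact interval 34.2% to 39.5%) against 27.0% of all rows, above their overall share but below the doubling set for a batch.

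The third pattern is the trend along the labelled A passages, with zinc finger genes among the falls, and of the 60 orders of the 5 passages, each counted once with its mirror, 1, the labelled one, gave as many rows (81), against 0 for the highest of the others. However, 3 pairs of mutual best partners lie at adjacent labelled passages, which 2 of the 60 orders keep, too few for a share under 0.05, and at an unadjusted p under 0.05 the labelled order gave 5405 rows and the highest other 5389. Loss of chromosome 19 as a whole is argued against. Its 939 other genes had a median slope of 0.011 log2 per 10 passages (95% bootstrap interval over genes 0.0074 to 0.014). The median was -0.22 for its 10 zinc finger genes that fell. Genes and not arrays were resampled, so the interval leaves out differences between arrays. The median of the other chromosome 19 genes was 0.0034 without A95 replicate 2, 0.017 without A39 replicate 2 and -2.4e-04 with median centring. Local loss of DNA that reaches the nearest other genes is argued against for the 12 zinc finger genes as a whole. The 33 nearest other genes had a median slope of -0.0018 (95% bootstrap interval over genes -0.013 to 0.032), against -0.26 for the 12. These neighbours were pooled over all loci, so loss at single loci stays open. On chromosome 12, ZNF605 and CHFR both fell, with slopes of -0.28 and -0.37, and the distance between them was not examined. The pooled neighbours left out all zinc finger genes and the dim rows under the 30th percentile. Loss confined to a stretch of zinc finger genes could therefore not be seen and stays open. Shared probes among related zinc finger genes and the doubt about the labels stay open, as does a decline of the 12 genes in long culture, which was not tested.

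The 227 chromosome 19 zinc finger genes that did not pass had a median slope of -0.050 log2 per 10 passages, with 169 negative, against a median of 0.0098 for all genes, and they were not tested as a set. With the 10 that passed, the median over 237 genes was -0.060, and the 256 zinc finger genes elsewhere had a median of -0.0084. The chromosome 19 median was -0.067 with quantile normalization and -0.072 with median centring, and it lay between -0.069 and -0.051 with an array left out.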
